A study of Homo sapiens with 4 samples.

How the data were processed

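Total RNA of A549 cells transfected with si-control or si-DLX6 was made into libraries from 1.3 µg of RNA with a SMARTER mRNA-Seq kit, per the labels' protocols, and cells were grown in medium with 10% serum. Small interfering RNA sequence, dose and time after transfection, as well as read length, strand use, aligner and counter, are not given in the sources used here. The authors deposited 1 table with 51136 rows and 1 value column per library. Per the file headers no unit is named, and the authors' values were taken as FPKM, reads divided by gene length and by the library total: the values of nearly all genes are whole multiples of a step of the gene, with the same ratio of steps between libraries. Whether reads or fragments were counted is not stated, and "reads" is used for both. The submitters' processing notes list a mouse build (GRCm38, mm10) for all 4 samples, yet the table pairs its rows with human symbols and human KEGG identifiers, so the build behind the values is not known and no coordinates were taken from the file. Positions in the text come from GENCODE release 29 (GRCh38) by gene symbol.

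Samples were grouped by the titles in the labels, and each column was matched to its sample by the column name that the sample's description gives. The labels name an adipogenic treatment for all 4 samples, which the titles and the transfection protocol do not mention. No value column was left unused. Rows at 0 in all libraries (22499) were left out, as were the 73 rows without a symbol from the genes that could be named.

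Dividing values by each gene's step recovered whole reads for 28632 of the 28637 genes above 0 (99.98% of positive values, within 0.01 reads). Library totals were set from mitochondrial genes, whose known lengths gave a common total in 11 of 13 cases. They came to 12075285 and 9678221 reads for si-control and 10485013 and 10665357 for si-DLX6, of which genes held 98.0% to 98.1%. If all of a gene's read numbers share a factor, the factor is lost. On simulated reads of 4868 genes, 96.4% came back exactly and 3.6% lost a factor. The 10 most abundant genes took 6.44% to 7.13% of reads. Between replicates of a group, reads differed by more than counting noise (chi-square per degree of freedom 6.80 and 8.12), so the 4 were counted as separate libraries, which leaves open whether those of a group came from the same RNA. Read ratios have exact 95% intervals, which cover counting error only.

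The design fixed before the data were examined assumed read counts, with a fallback for normalized values. Since the file holds FPKM, the fallback was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), group as the only term, for the 15504 genes with at least 1 FPKM in at least 2 libraries, with Benjamini-Hochberg adjustment. Fold changes are on that scale, which understates the change of low genes, and SE is limma's moderated standard error. Genes were called at an adjusted p under 0.05. On simulated reads for the same libraries (15107 genes tested, dispersion 0.0131), this test called 3.03% of 66 genes changed 1.5-fold, 49.2% of 65 genes changed 2-fold and 92.1% of 63 genes changed 4-fold. It made 124 calls, of which 32 were false, above the 5% aimed at; 0 of the 32 had a mean of at least 50 reads, so calls of genes with few reads are less reliable. limma-voom on the same simulated reads made 125 calls with 2 false ones, and called 25.8%, 72.3% and 93.7% of the 3 sets. Few genes were changed in the simulation, while 3046 were called in the data. A call in the simulation therefore needed a smaller unadjusted p, and these shares do not carry over to the data.

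Gene lists (39, fixed before the data were examined, 955 gene names) were matched to rows by symbol or Entrez identifier. The 34 lists with at least 5 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. With an estimated correlation, camera also judges a list on the few degrees of freedom that 4 libraries leave, so a list could hardly pass. In the simulation 0 of 20 unchanged lists were called by camera. Its genes were drawn independently, so this does not cover lists whose genes move together, such as ribosomal proteins (estimated correlation 0.60). Genes were named in the text by a rule: the tested genes of the DLX list, and the 12 largest rises and 12 largest falls among called genes with a symbol, a mean of at least 10 FPKM and both si-DLX6 libraries beyond both si-control libraries. For each list past camera, up to 4 members by smallest p were added, giving 87 genes. Genes outside it that are named (*HMOX1*, *HIST1H2BH*, *DDIT3*, *TRIB3*, *FBN1*, *SPARC*, *CD68*, *DLX3*, *DLX6-AS1*, and members of lists that did not pass camera or of symbol families) were chosen after their values were seen.

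Alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter of 50 recovered reads in 2 libraries, the replicate number as a block, leaving out each library, limma-voom on recovered reads, a pseudocount of 0.1, an adjusted p limit of 0.01 and a test against a log2 fold change of 0.5 (treat). Protein-coding genes alone, and removal of a GC and length trend, were added after seeing the data. Words of 7 bases were searched in the 3′ UTRs of GENCODE transcripts of 10665 tested genes with at least 50 bases of 3′ UTR, in a regression of log2 fold change on presence of the word with UTR length and GC content as covariates (Python 3.11.15, numpy 2.4.6). The lowest and highest z over 100 permutations of the fold changes over genes were −4.55 and 4.92. The searched genes were also split at random into 2 sets of nearly equal size 20 times, and the word with the lowest z in each set was measured in the other.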

Results

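RNA-seq measured transcript levels in A549 cells, an established human lung adenocarcinoma line, after transfection with a small interfering RNA against *DLX6* (si-DLX6) or a control small interfering RNA (si-control). *DLX6* encodes a distal-less homeobox transcription factor best known from limb and craniofacial development. The comparison asked which transcripts differ when *DLX6* is knocked down, and it rested on 2 si-control and 2 si-DLX6 libraries. The labels do not say that the 2 libraries of a group came from separate cultures. Each p-value of a single gene therefore measures only the spread between these libraries, which may be technical. A list's camera p-value with the preset correlation instead compares its genes with other genes. Genes rather than libraries act as the replicates there. The si-control libraries held 12075285 and 9678221 reads and the si-DLX6 libraries 10485013 and 10665357 reads, as recovered from the deposited values. Of 51136 genes in the table, 24039 and 23520 were above 0 in the si-control libraries, and 24931 and 25315 in the si-DLX6 libraries. Across the 15504 genes tested, the median absolute log2 difference was 0.16 between the si-control libraries and 0.17 between the si-DLX6 libraries. Between libraries of different groups it was 0.28 to 0.32. Pearson correlations across genes, which are not independent replicates, were 0.986 and 0.984 within groups and 0.958 to 0.965 between groups.

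*DLX6*, the targeted gene, fell from 3.37 ± 0.144 FPKM (SD, n = 2) with si-control to 0.683 ± 0.329 FPKM (SD, n = 2) with si-DLX6, a 4.94-fold difference. The si-control libraries gave 3.27 and 3.47 FPKM and the si-DLX6 libraries 0.916 and 0.450 FPKM, so the level of the targeted gene followed the labels in all 4 libraries. The values rest on 74 and 63 reads against 18 and 9 reads. Per library total, the si-DLX6 reads were 20.3% of the si-control reads (95% exact interval 12.9% to 30.8%, counting error only). The log2 fold change was −1.39 (SE 0.20), with an adjusted p of 0.00859 (limma, Benjamini-Hochberg). With no filter on low values the adjusted p was 0.0667, and in a test against a log2 fold change of 0.5 it was 0.0928. The log2 fold change was −2.34 by limma-voom on recovered reads and −2.21 with a pseudocount of 0.1. In GENCODE release 29 (GRCh38), *DLX6* lies on chromosome 7 from 97005548 to 97011039 on the plus strand, within the span of the antisense gene *DLX6-AS1* (96955141 to 97014065, minus strand). Whether the counting used strand is not given in the sources used here, so reads of this pair cannot be separated. *DLX6-AS1* had 6 and 7 reads with si-control and 11 and 18 with si-DLX6, below the filter for testing.

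Another family member, *DLX2*, fell from 2.30 ± 0.302 FPKM (SD, n = 2) to 0.718 ± 0.0204 FPKM (SD, n = 2), a log2 fold change of −0.94 (SE 0.18; adjusted p = 0.0169, limma, Benjamini-Hochberg). It had 58 and 56 reads against 17 and 18 reads, or 31.6% of si-control (95% exact interval 21% to 46.5%). Without si-control library 2 its adjusted p was 0.0717. With all libraries its log2 fold change was −1.63 by limma-voom and −1.55 with a pseudocount of 0.1. Its 3′ UTR holds the word ATCCTCA, which is among the 2788 of 16106 searched words that also occur in the *DLX6* transcript. This word stood out in a search on these same fold changes, so its presence here is no separate support for a seed match. The 3′ UTR of *SHFM1* holds ATCCTCA as well and that of *DLX1* the shorter TCCTCA, and neither gene was called. *DLX2* lies on chromosome 2 from 172099439 to 172102900, beside *DLX1* (172084740 to 172089677). *DLX1*, at 94.3% of si-control reads (80.6% to 110.4%), *DLX4*, at 119.6% (89.7% to 159.8%), and *DLX5*, the chromosome 7 neighbour of *DLX6*, at 154% (98.0% to 246%), did not pass the test, with limma adjusted p of 0.775, 0.463 and 0.271. The locus neighbours *SHFM1* (113%, adjusted p = 0.289) and *SDHAF3* (72.9%, adjusted p = 0.0749) did not pass either. *DLX3* had 1 read in 1 library. Of the 7 tested genes of the list of DLX family and *DLX6* locus genes, 0 were higher and 2 lower (3 lower adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.320).

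**Figure D1:**
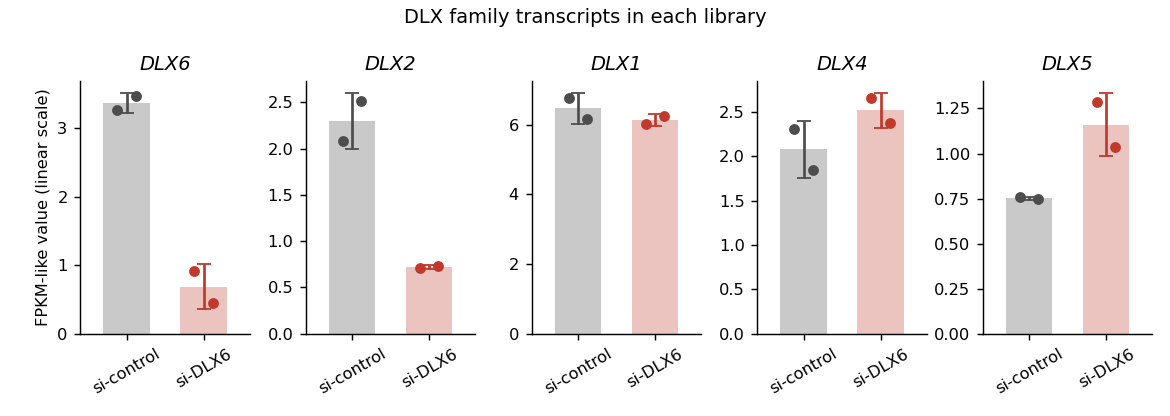
FPKM values on a linear scale of 5 DLX family transcripts in the 2 si-control and 2 si-DLX6 libraries; points are libraries, bars are group means and whiskers are SD. *DLX6* falls from a mean of 3.37 to 0.683 and *DLX2* from 2.30 to 0.718, while the other 3 genes did not pass the test.

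Among genes with a mean of at least 10 FPKM, the 12 largest falls included transcripts of the mitochondrial chaperone *HSPD1*, the splicing-complex assembly factor *CLNS1A*, the membrane-cytoskeleton linker *MSN*, the histone chaperone subunit *SSRP1* and the citrate lyase *ACLY*, and the 12 largest rises included *BFSP1*, *NTM*, 3 histone genes, *APOE* and *SERPINA1*. Of 15504 genes tested, 3046 (19.6%) had an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1575 higher and 1471 lower with si-DLX6. More genes were lower than higher under other scalings, with 1257 higher and 1627 lower by median-of-ratios and 1289 and 1517 by upper-quartile scaling. A log2 fold change of at least 1 was reached by 339 of the higher and 261 of the lower genes. An unadjusted p under 0.05 was found for 5598 genes. The groups did not overlap in 63.0% of genes, where chance gives 33.3%. Among protein-coding genes, 1210 were higher and 1095 lower. Leaving out 1 library reduced the count to 1623 without si-control 1, 1365 without si-control 2, 1658 without si-DLX6 1 and 1689 without si-DLX6 2, and no called gene changed direction. With no filter on low values 372 genes were called, and with an adjusted p limit of 0.01, 658.

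The largest fall among genes of at least 10 FPKM was that of *CLNS1A*, from 66.0 ± 2.52 to 9.88 ± 0.0269 FPKM (SD, n = 2 each; log2 fold change −2.62, SE 0.10, adjusted p = 0.000542, limma, Benjamini-Hochberg). *HSPD1* fell from 393 ± 16 to 66.5 ± 1.02 FPKM (log2 fold change −2.55, SE 0.09). The processed copies *HSPD1P1* (−2.61) and *HSPD1P4* (−2.16) are near-identical to it in sequence, so reads of these 3 genes may have been shared and the copies are uncertain. *RAD23B*, a DNA repair and proteasome shuttle factor, fell by 2.20 on the log2 scale, *MSN* by 2.14, the nuclear receptor *NR2F6* by 2.09, *SSRP1* by 2.01, *ACLY* by 2.00 and *FAM89B* by 1.85. The remaining 2 of the 12 largest falls were the short RNAs *BCYRN1* (−1.97), a repeat-derived transcript with many near-copies, and *SNORD25* (−1.87). *BCYRN1* had 58 and 28 reads with si-control and 8 and 9 with si-DLX6. *SNORD25* had 42 and 49 against 9 and 15 reads, and calls at so few reads are less reliable. The 3′ UTRs of *CLNS1A* and *MSN* hold TCCTCAA and that of *SSRP1* holds ATCCTCA, 3 of the 8 of these falls whose 3′ UTR was searched. The shorter word TCCTCA occurs in 7 of the 8, all except *RAD23B*. Of the 8 searched genes among the 12 largest rises 1 holds TCCTCA (*SERPINA1*, as ATCCTCA). Of all 10665 searched genes 35.2% hold TCCTCA and 15.7% hold ATCCTCA or TCCTCAA. These words came from a search on the same fold changes, so their presence among the largest falls is no separate support. Of the 25 searched falls with the smallest p (limma), 7 hold ATCCTCA or TCCTCAA, and of the 25 such rises 3 do. None of these counts takes UTR length into account.

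Among rises, the lens filament gene *BFSP1* went from 8.81 ± 0.519 to 36.8 ± 3.32 FPKM (SD, n = 2 each; log2 fold change 1.94, SE 0.12, adjusted p = 0.00179, limma, Benjamini-Hochberg) and the neural adhesion gene *NTM* from 5.50 ± 0.0587 to 23.9 ± 2.98 FPKM (1.93, SE 0.13). *APOE*, the apolipoprotein of lipid transport, rose from 17.1 ± 1.5 to 62.3 ± 3.02 FPKM (1.81, SE 0.11), and the protease inhibitor *SERPINA1* from 4.38 ± 0.0564 to 17.1 ± 1.49 FPKM (1.75, SE 0.13). The other genes of the 12 largest rises were the histone genes *HIST1H3H* (1.93), *HIST1H2BD* (1.91) and *HIST1H2BC* (1.84), *C19orf33* (1.85), *FTH1P2* (1.76), *TRIM16L* (1.74), *ACOT1* (1.73) and *RN7SK* (1.73). *FTH1P2* is a processed copy of *FTH1*, *TRIM16L* a pseudogene related to *TRIM16*, and *ACOT1* has the near-identical neighbour *ACOT2*, so their values are uncertain. *RN7SK* rested on few reads, 23 and 13 with si-control and 43 and 95 with si-DLX6.

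**Figure D2:**
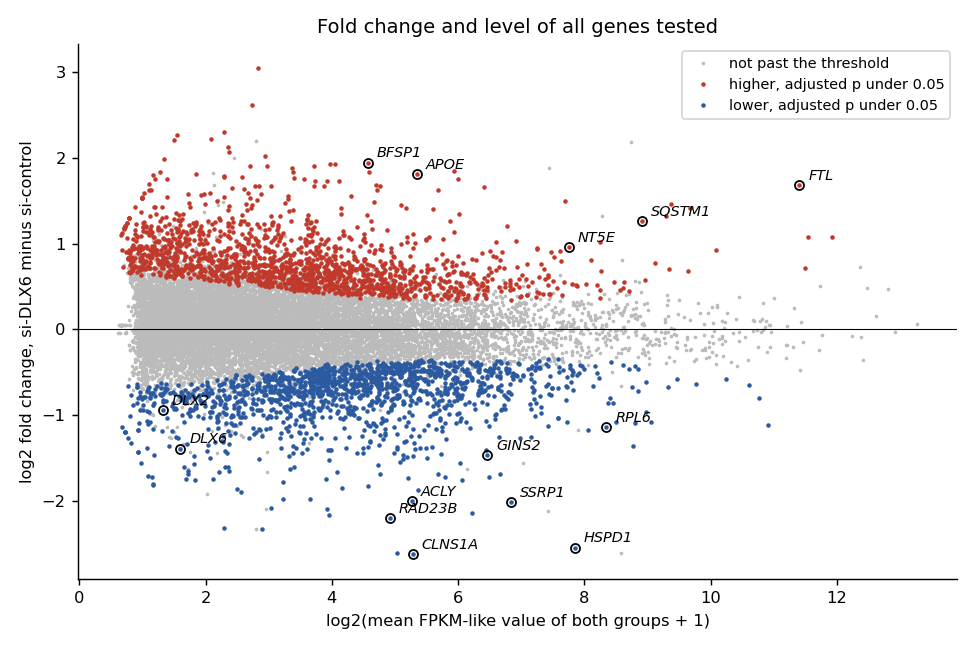
Each point is 1 of 15504 genes; the horizontal axis is the log2 mean FPKM of both groups plus 1 and the vertical axis the log2 fold change, si-DLX6 minus si-control. Red marks the 1575 higher and blue the 1471 lower genes with an adjusted p under 0.05; *HSPD1* at −2.55 and *FTL* at 1.68 stand out among abundant transcripts.

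**Figure D3:**
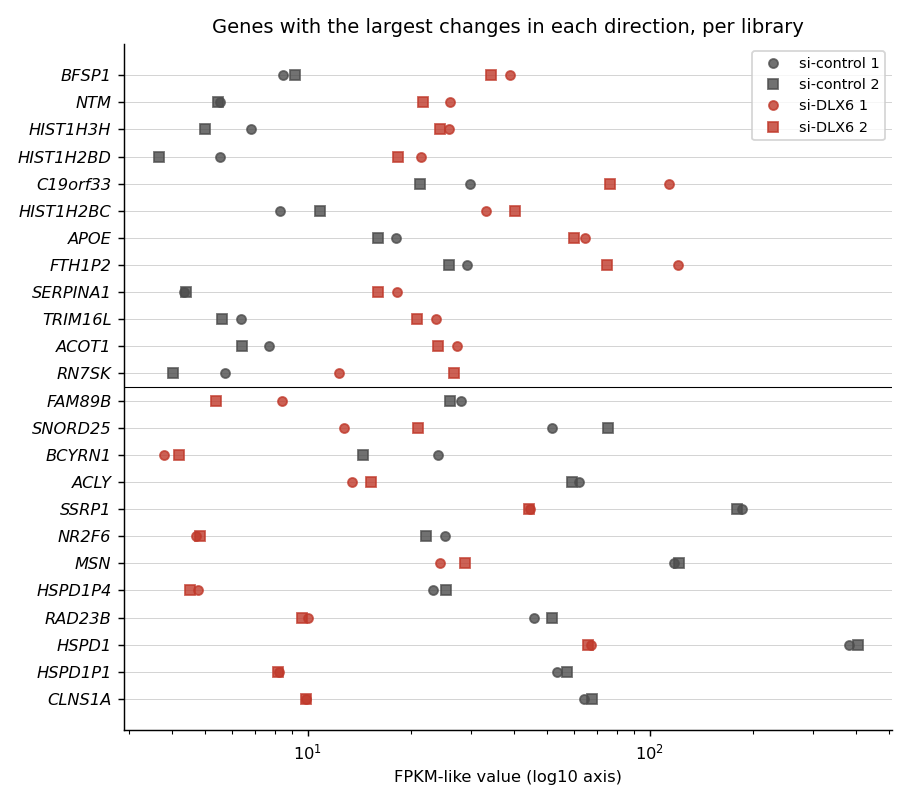
FPKM values on a log10 axis of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom) among genes of at least 10 FPKM, 1 symbol per library. In each of them both si-DLX6 libraries lie beyond both si-control libraries, as the selection required.

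In the fixed lists of DNA replication, MYC target and mitosis genes, many members fell with si-DLX6 and 0 rose, though none of these lists stood apart with an estimated correlation. Of 40 tested genes of G1/S and DNA replication, 28 fell and 0 rose (34 and 0 adjusted over the list alone), with a median log2 fold change of −0.65. Examples were the replicative helicase subunits *MCM2* (−0.92) and *GINS2* (from 127.9 to 45.8 FPKM, −1.47), the polymerase clamp *PCNA* (−0.94) and the cohesion factor *DSCC1* (−1.62). The list stood apart in camera (adjusted p = 8.05e-17, Benjamini-Hochberg), but not with an estimated correlation (adjusted p = 0.297). Of 28 MYC target genes 20 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of −0.61. The nucleolar factors *NOLC1* (−1.69) and *MRTO4* (−1.45) and the mitochondrial RNA-binding factor *TBRG4* (−1.14) are examples beside *HSPD1* (camera adjusted p = 1.14e-14; 0.297 as adjusted p with an estimated correlation). Of 40 G2/M and mitosis genes, 18 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of −0.41. Among them were the transcription factor *FOXM1* (−0.85), the phosphatase *CDC25B* (−0.91) and the kinase *PLK1* (−0.76). The camera adjusted p was 5.84e-10, and 0.590 as adjusted p with an estimated correlation.

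Replication-dependent histone transcripts, which are made in S phase and mostly lack a poly(A) tail, went the other way. Of 22 tested, 10 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.80. The median was 1.66 with the filter of 50 recovered reads, 1.38 with a pseudocount of 0.1 and 0.54 with no filter. *HIST1H2AE* went from 3.58 to 15.4 FPKM (1.84), and *HIST1H2BH*, at −0.49, was the 1 that fell. Histone genes share much of their coding sequence, so single members are uncertain. The camera adjusted p was 0.00143, and 0.422 as adjusted p with an estimated correlation. Other RNAs without a poly(A) tail moved apart from each other. The median of 13 scaRNAs was 1.13 (7 higher, 0 lower), or 0.55 for the 7 of them above 0 in all 4 libraries. Of 13 genes named RNU or *RN7SK* 4 were higher and 0 lower, and of 169 snoRNAs 8 were higher and 33 lower, with a median of −0.28. *RN7SK* was at 4.89 ± 1.20 FPKM (SD, n = 2) with si-control and 19.6 ± 10.2 (SD, n = 2) with si-DLX6.

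Targets of NRF2, the transcription factor of the antioxidant response, which a *KEAP1* mutation is known to keep active in A549 cells, rose more often than they fell. Of 26 tested, 16 rose and 1 fell (17 and 3 adjusted over the list alone), with a median of 0.72. The ferritin light chain *FTL* went from 1280 ± 1.55 to 4131 ± 516 FPKM (SD, n = 2 each; log2 fold change 1.68, SE 0.15, adjusted p = 0.00325, limma, Benjamini-Hochberg). *OSGIN1* (1.67) and *PIR* (1.17) rose as well, and the heme oxygenase *HMOX1* (−0.52) was the 1 that fell. The camera adjusted p was 5.10e-07, and 0.297 as adjusted p with an estimated correlation. Of 27 autophagy and lysosome genes, 11 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.31. The autophagy receptor *SQSTM1* went from 282 ± 4.93 to 677 ± 13.6 FPKM (SD, n = 2 each; 1.26) and *GABARAPL1* from 25.5 to 50.5 FPKM (0.95), while *ATG9A* fell (−0.85). The camera adjusted p was 0.00316, and 0.422 as adjusted p with an estimated correlation.

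In lists of signalling targets and of mesenchymal genes more members rose than fell. Of 20 YAP-TEAD targets 5 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.38), among them *LATS2* (1.47), *CTGF* (0.85) and *NT5E* (0.96), with a camera adjusted p of 0.00187, and 0.628 as adjusted p with an estimated correlation. Of 16 TGF-beta targets 7 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.51), among them *CTGF*, which both lists hold, and *TGFBI* (0.73), while *ANGPTL4* fell (−0.94). The ligand *TGFB1*, of the same 16 genes, went from 57.2 ± 2.69 to 107 ± 1.5 FPKM (SD, n = 2 each; 0.89). The TGF-beta list had a camera adjusted p of 0.0102, and 0.628 as adjusted p with an estimated correlation. Of 8 BMP-SMAD targets 4 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.61, or 0.22 with no filter), with a camera adjusted p of 0.00458, and 0.628 as adjusted p with an estimated correlation. These were *ID2* (0.94), *ID1* (0.72), *ID3* (0.51) and *ATOH8* (0.70), of which *ID1* and *ID3* lost their calls in 2 and *ATOH8* in 4 of the 4 fits without 1 library (limma adjusted p from 0.0721 to 0.125 in those fits). *ID1* was at 0.48 without si-control 2, and *ATOH8* at 1.14 by limma-voom and 1.07 with a pseudocount of 0.1. Of 19 mesenchymal and EMT markers 7 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.35, or 0.55 with a pseudocount of 0.1), among them the matrix genes *FBN1* (0.91) and *SPARC* (0.77), with a camera adjusted p of 0.0102, and 0.628 as adjusted p with an estimated correlation. Of 13 epithelial markers, 4 rose (*CLDN1*, *TJP3*, *MUC1* and *LAMB3*) and 0 fell (5 and 0 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.143). Its median of 0.25 was 0.51 without si-DLX6 1, 0.14 without si-control 1 and 0.15 with no filter. Of 25 interferon-stimulated genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.32), among them *ISG15* (0.84), *IFIT2* (1.19, or 2.02 by limma-voom and 1.86 with a pseudocount of 0.1) and *IFIT3* (1.08). The interferon list had a camera adjusted p of 0.0142, 0.0570 without si-control library 1, and 0.628 as adjusted p with an estimated correlation.

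In metabolic and inflammatory lists more members fell than rose. Of 21 fatty acid synthesis genes 7 fell and 1 rose (10 and 3 adjusted over the list alone; median −0.27), led by *ACLY* and the elongase *ELOVL1* (from 137 to 41.0 FPKM, −1.72), with a camera adjusted p of 0.0142, and 0.628 as adjusted p with an estimated correlation. The median was −0.12 without si-DLX6 1. The word TCCTCA occurs in the 3′ UTRs of 11 of the 21, *ACLY* and *ELOVL1* among them, and the other 10 had a median of 0.044. Of 25 genes of amino acid synthesis and the ATF4 response 8 fell and 4 rose (8 and 5 adjusted over the list alone; median −0.26). Those that fell included the amino acid transporter *SLC7A5* (−1.39), *PSAT1* (−1.18) and *ASNS* (−0.98), whereas the stress regulators *DDIT3* (0.72), *TRIB3* (0.82) and *SESN2* (0.77) rose. This list had a camera adjusted p of 0.0182, 0.112 without si-control 1, 0.0566 without si-DLX6 2, and 0.628 as adjusted p with an estimated correlation. Of 32 nuclear genes of oxidative phosphorylation 6 fell and 1 rose (8 and 2 adjusted over the list alone; median −0.19), with a camera adjusted p of 0.00446, 0.0727 without si-DLX6 2, and 0.628 as adjusted p with an estimated correlation. *CYC1*, of complex III, had a log2 fold change of −0.66 and limma adjusted p of 0.0186, which was 0.0720 without si-control 1 and 0.0587 without si-DLX6 2. Of 14 NF-kappaB and inflammatory genes 3 fell and 0 rose (4 and 0 adjusted over the list alone; median −0.31), with a camera adjusted p of 0.0142, and 0.590 as adjusted p with an estimated correlation. These were *ICAM1* (−0.69), *BIRC3* (−0.66) and *NFKB2* (−0.42). Each lost its call in all 4 fits without 1 library (limma adjusted p from 0.0582 to 0.185), except *ICAM1* without si-DLX6 1. The median of this list was −0.19 without si-DLX6 1 and −0.059 with no filter.

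Cytosolic ribosomal protein transcripts differed little as a group. Of 49 tested, 4 fell and 0 rose (3 and 0 adjusted over the list alone), namely *RPL6* (from 447 to 203 FPKM, −1.14), *RPL13A* (−1.07), *RPS14* and *RPS23*, and the median was −0.065. The list had a camera adjusted p of 0.0142, and 0.831 as adjusted p with an estimated correlation. Its median turned to 0.049 without si-control 1 (camera adjusted p = 0.532) and to 0.065 without si-DLX6 2 (camera adjusted p = 0.859), and it was −0.20 without si-control 2 or si-DLX6 1. It was −0.12 and −0.11 with median-of-ratios and upper-quartile scaling. *RPS14* lost its call in 2 and *RPS23* in 4 of the 4 fits without 1 library (limma adjusted p from 0.0659 to 0.142). The word TCCTCA occurs in the 3′ UTRs of *RPL13A*, *RPS14* and *RPS23*, and that of *RPL6* was not searched. Of the 33 members searched, 7 hold the word. Ribosomal protein genes have many processed copies, so single values are uncertain.

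**Figure D4:**
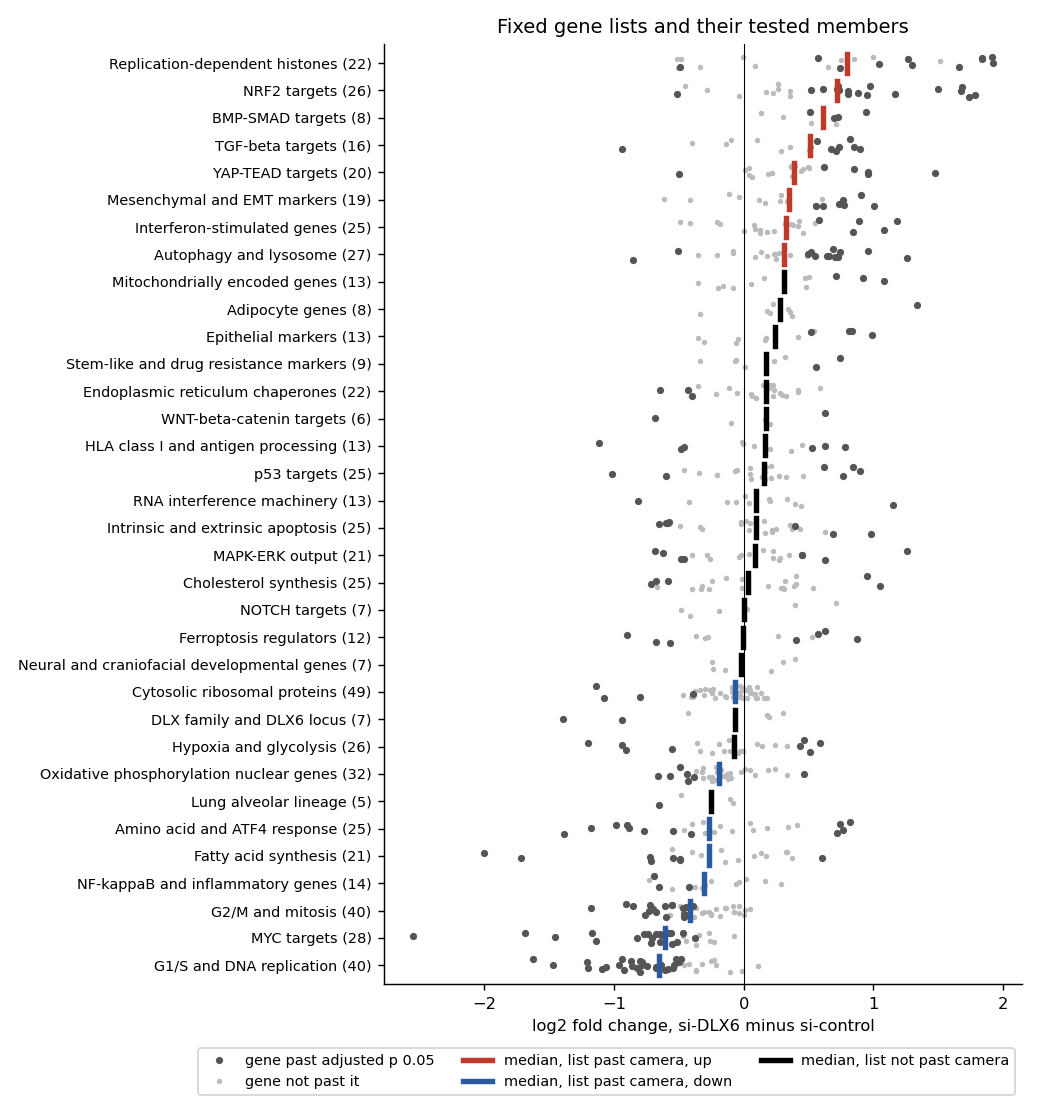
Log2 fold changes (si-DLX6 minus si-control) of the tested members of 34 fixed gene lists; each point is a gene, dark where its adjusted p was under 0.05, and each thick line is the list's median. Numbers in parentheses are members tested; histones (median 0.80) and NRF2 targets (0.72) lie at the top and G1/S and DNA replication (−0.65) at the bottom.

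Of 34 lists tested, 16 passed camera at an adjusted p under 0.05 with the preset correlation, 8 up and 8 down. None did with an estimated correlation, where 0.297 was the smallest adjusted p, but with 4 libraries that setting could hardly be passed. The MYC target list had an estimated correlation of −0.021, below the preset 0.01, and its unadjusted camera p still went from 6.72e-16 to 0.0118. For the ribosomal protein list the estimated correlation was 0.60. Failing this setting alone therefore does not show that correlation between genes explains a call. By fry, which asks whether a list's genes moved one way on balance, 6 of the 16 held: G1/S and DNA replication (adjusted p = 0.0205), MYC targets (0.00677), NRF2 targets (0.00677), histones (0.00998), autophagy and lysosome (0.00998) and TGF-beta targets (0.0413). Lists that did not pass camera included p53 targets (25 tested, 4 higher, 2 lower), where *TNFRSF10B*, *TNFRSF10C*, *TP53INP1* and *SESN2* rose, *PMAIP1* and *AEN* fell and the cell cycle inhibitor *CDKN1A* was at 0.05, and apoptosis genes (25 tested, 3 higher, 4 lower). Also not past it were MAPK-ERK output (21 tested, 4 higher, 4 lower), hypoxia and glycolysis (26 tested, 4 higher, 4 lower), ferroptosis regulators (12 tested, 4 higher, 3 lower), HLA class I and antigen processing (13 tested, 3 higher, 3 lower) and cholesterol synthesis (25 tested, 2 higher, 3 lower). The 22 chaperones of the endoplasmic reticulum had 0 higher and 3 lower (*SDF2L1*, *HSP90B1* and *SEC61B*), the 6 WNT targets 1 (*CCND1*) and 1 (*MYC*), the 7 NOTCH targets 0 and 0, the 13 RNA interference genes 1 (*TNRC6A*) and 1 (*XPO5*), and the 9 stem-like and drug resistance markers 2 (*KLF4* and *ABCC1*) and 0. The 13 mitochondrially encoded genes had 3 higher (*ND1*, *ND2* and *ND5*) and 0 lower, the 5 lung alveolar genes 0 and 1 (*ABCA3*), and the 7 neural and craniofacial genes 0 and 0. Median, mean and camera direction differed in sign for the cholesterol, ferroptosis, NOTCH and neural lists, and the chaperone list had a median of 0.17 although its 3 called genes were lower.

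Markers of other cell types were mostly near or below the filter. Of 8 adipocyte genes tested, 1 (*ADIRF*) was higher and 0 lower (camera adjusted p = 0.155). The labels give an adipogenic treatment for all 4 libraries, so it does not differ between the groups. Endothelial markers had 1 tested gene, erythroid markers 0, fibroblast markers 2, gastrointestinal and hepatic genes 2 and leukocyte markers 1, too few for a list test. Of these 6 genes, *SERPINA1*, *ACTA2* and *CD68* were higher and 0 were lower. *ACTA2*, also in the mesenchymal list, lost its call without si-control 2 (limma adjusted p = 0.0659) and without si-DLX6 1 (0.0611). The most abundant of the 6 was the lysosomal glycoprotein gene *CD68*, with a mean of 88.5 FPKM over all libraries.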

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

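The tests with protein-coding genes alone and with a GC and length trend removed were chosen after the result was seen. The count-model tests planned for a file of counts were not run. Since the file holds FPKM, the planned fallback was used, and limma-voom on recovered reads was the only count-based alternative. In the other settings no called gene and no called list changed direction, except the ribosomal protein list, whose median of −0.065 turned to 0.049 without si-control 1 and 0.065 without si-DLX6 2 and ranged from −0.20 to 0.065 over the fits without 1 library. The 16 called lists stayed called under both scalings, with no filter, the strict filter, the block, a pseudocount of 0.1, protein-coding genes and the GC and length correction; 13 stayed without si-control 1 and 13 without si-DLX6 2. With an estimated correlation, a setting that could hardly be passed with 4 libraries, 0 lists were called, and by fry 6. Of the 80 called genes named by the rule besides *DLX6*, 35 lost their call with no filter, 44 by treat, and 12 to 15 without 1 library.

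The count of 3046 genes fell to 372 with no filter (167 higher, 205 lower; with a log2 fold change of at least 1, 101 and 117), where low genes enter the variance trend and the adjustment. With the strict filter 12634 genes were tested and 3759 called, of which 222 rose by at least 1. All 2614 genes of the main calls that stayed in this test kept their call. The large rises that dropped out were therefore those of genes with too few reads for this filter. Without 1 library the count was 1365 to 1689 (682 to 852 higher, 683 to 915 lower), with 3 libraries and the lone one assumed to vary like the other group. An adjusted p limit of 0.01 left 658 (286 higher, 372 lower, 199 higher by at least 1), and treat 168 (76 higher and 92 lower). Rises of at least 1 numbered 680 by limma-voom and 559 with a pseudocount of 0.1, as both shrink low genes less. Protein-coding genes gave 181 rises and 158 falls of at least 1. With the GC and length trend removed 4717 genes were called (2446 lower); the cause was not tested. Median-of-ratios scaling moved the share of higher genes from 51.7% to 43.6%. *DLX6*, at −1.39, was −2.34 by limma-voom, −2.21 with a pseudocount of 0.1 and −1.59 to −1.19 without 1 library. Its adjusted p was 0.0667 with no filter and 0.0928 by treat, and it passed the threshold in its other fits (limma, Benjamini-Hochberg). The mean of the median absolute log2 difference between groups, 0.31, was 0.36 with a pseudocount of 0.1 and 0.29 with the strict filter.

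The labels number the libraries 1 and 2 in both groups, but with 2 pairs and no stated shared day or batch the numbers were not read as pairs; the correlation of deviations of same-numbered libraries was 0.20. With the replicate number as a block, 5119 genes were called (2749 higher, 2370 lower). Depth limits the low genes: 1 read in a gene of 1 kb is worth 0.0828 to 0.103 FPKM.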

Other observations

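The test of the leading 3′ UTR word in separate sets of genes, the split of small RNAs by class, and the tests of gene families by shared symbol stem were chosen after the result was seen. The GC and length test was added after the main result, and the TCCTCA checks of gene lists after the word search. The remaining tests were fixed before their values were seen. Of 177 families of tested genes that share a symbol stem, 8 stood apart from other genes in camera at an adjusted p under 0.05. None did with an estimated correlation (camera adjusted p = 0.986), a setting that could hardly be passed with 4 libraries. Of 9 TOMM genes, named for the translocase of the outer mitochondrial membrane, 5 fell and 0 rose, among them *TOMM40* (−0.76), *TOMM34* (−0.75) and *TOMM22* (−0.70). The 14 TIMM genes, named for the translocase of the inner membrane, did not stand apart (0 higher, 2 lower; camera adjusted p = 0.558). Of 48 MRPL genes, which encode mitochondrial ribosomal proteins, 12 fell and 1 rose, and of 29 MRPS genes 8 fell and 1 rose, while most members of both stems did not pass the test. Of 20 genes of the NUP stem, nucleoporins besides *NUP62CL*, 6 fell and 0 rose, with *NUP37* at −0.63 and *NUP205* at −0.62. Of 8 RRP genes, which act in ribosomal RNA processing, 3 fell and 0 rose, among them *RRP9* (−1.16) and *RRP7A* (−1.10), and 2 of the 8 are also in the MYC target list. Of 9 annexin genes, which encode calcium-dependent membrane-binding proteins, 7 rose and 0 fell, with *ANXA1* at 0.56, *ANXA3* at 0.71 and *ANXA9* at 0.77, and the tenth gene of the stem, *ANXA2R*, is not an annexin (0.039). The MCM stem (7 of 10 lower) shares 7 genes with the fixed replication list. The HIST stem (16 of 39 higher, 1 lower) shares 22 with the fixed histone list, and of its 17 other genes 6 were higher and 0 lower.

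For the genes changed with si-DLX6, a GC or length bias as the whole cause was argued against. Of the 2773 called genes with both values, 98.85% kept their call and direction once the trend was removed. That fit called more genes (4717 against 3046), so a kept call does not show how much of a fold change was kept. A part played by such a bias stays open. Among 16106 words of 7 bases in 3′ UTRs, TCCTCAA (z = −12.1) and ATCCTCA (z = −10.2) went with the lowest fold changes, below the lowest permuted z of −4.55; ATCCTCA occurs in the *DLX6* transcript and ranked 2, so rank 1, asked beforehand of a seed match of the si-DLX6 guide strand, was not reached, and a word absent from the transcript lay lower, which was set against it together with a rank above 10. TCCTCAA shares 6 bases with ATCCTCA, so its lower z does not exclude a shared seed and this test stays open. In 20 random splits of the genes into 2 sets of nearly equal size, the word with the lowest z in either set was TCCTCAA. Its z was −7.09 or lower in the set that did not choose it (−1.67 to 2.62 for permuted fold changes), in the same 4 libraries. TCCTCAA already had the lowest z over all these genes, so the splits add only that its z does not rest on a few genes. Mean log2 fold changes, adjusted for UTR length and GC content, were also set against those of genes without TCCTCA. The difference was −0.23 with ATCCTCAA, −0.13 with ATCCTCA only, −0.16 with TCCTCAA only and −0.038 with TCCTCA only. The words were chosen on these fold changes, so this order is no separate test. A guide strand whose seed pairs with TCCTCA is a hypothesis that goes with these words. The sequence is not given in the sources used here, and other factors that bind the word were not tested. An excess of 83.1 among 1056 searched lower genes (7.87%) goes with the 7-base forms. That count leaves out genes with only the 6 shared bases and was not adjusted for UTR length or GC content. The share of falls that goes with the word is therefore not known. For the other falls, loss of *DLX6* and other effects of the transfected RNA both stay open.

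In the histone list more transcripts rose (10 of 22) than fell (1), while in the replication list 28 of 40 fell and 0 rose. A scaling artifact was argued against, since both lists kept at least 96.0% of their median under 2 other scalings. Seed matches to TCCTCA as the cause of the fall of the replication list were argued against too. Only 8 of its 40 members hold the word in the 3′ UTR, and the 32 without it kept 86.4% of the list's median, with 21 called. The word was found in the same fold changes, and other seeds were not tested. Not each list kept its fall without the word. Members that lack TCCTCA had a median of 0.044 in the fatty acid list, against −0.27 over all its members. In the ribosomal protein list their median was −0.027, against −0.065 over all its members, and 0 of those 26 were called. More RNA without a poly(A) tail in the si-DLX6 libraries stays open: the median of 195 snoRNA, scaRNA and snRNA genes was −0.084, under the bound set beforehand against it, but that bound pooled classes that moved apart, with snoRNAs at −0.28 and scaRNAs at 1.13. A biological difference between the groups therefore cannot be told apart from a change in captured RNA for the histone genes.

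More NRF2 targets rose (16 of 26) than fell (1), and the list stood apart in camera with the preset correlation but not with an estimated one (adjusted p = 0.297 with an estimated correlation). The rise of the list did not rest on the ferritin genes, whose reads may be shared with processed copies. Without *FTH1* and *FTL* the other 24 members kept 92.1% of its median (0.66, camera adjusted p = 7.84e-06, and adjusted p = 0.364 with an estimated correlation). A median depends little on so few members, and whether ferritin reads were shared was not tested. A change set by 1 library was argued against, since the fits without each library kept at least 84.6% of the list's median. A higher activity of NRF2 with si-DLX6 may therefore be a biological difference, as a hypothesis found and tested on the same data, and *HMOX1*, at −0.52, goes against it. Whether it follows from lower *DLX6* or from another effect of the transfected RNA was not tested.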
